A study of Mus musculus with 12 samples.

How the data were processed

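The series holds 12 RNA sequencing libraries of dermal papilla cells sorted by FACS from mice, 3 in each of 4 groups: wild type (WT) and Smo gain-of-function mutant (Smo*) at postnatal day 20 (telogen, females) and at postnatal day 28 (anagen, males). Total RNA was purified with the RNeasy Plus Micro kit, ribosomal RNA was removed from 100 ng, and libraries were made with a kit that marks the strand (NEBNext Ultra Directional), per the labels' protocols. The tools Trimmomatic, TopHat2 (version 2), HTSeq and DESeq2 and the builds mm10 and GRCm38.p4 are named per the submitters' processing notes, which give no roles or order. Whether counting used the strand is not given in the sources used here, so reads of a gene and an antisense or overlapping partner may be joined, and near-identical copies such as Hspa1a and Hspa1b or the alpha-globin genes are uncertain.

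Each of the 2 deposited tables, 1 per age, holds a normalized read count (unit: signal) for 25887 genes in 6 libraries, made by the authors by dividing counts by 1 size factor per library. This was read from the values: in each library 100% of the values were whole multiples of 1 step, within 0.01 reads, so whole reads were recovered. The mean column that the authors deposited equals the mean over all 12 libraries in both tables, so the libraries were normalized together, although the tests had been laid out for tables normalized separately. The same deposited tables hold the authors' log2 fold change with its standard error on the log2 scale, which is WT over Smo* (the sign matched the values in 100% of the genes called there), their test statistic (a score), their p-value and their adjusted p-value.

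Gene symbols came from a GENCODE release of GRCm38, the same build, which named 98.7% of the identifiers (25562). All columns were matched to a sample through the number in its title, leaving 0 columns unused. The labels give no replicate numbers, so replicates are numbered in accession order only. The titles carry a number per sample that no other shares and whose meaning is not stated, so the main test made no pairs.

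The main test at each age was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1), over the 6 libraries of that age and genes with a mean of at least 10, with Benjamini-Hochberg adjustment at a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. They are given as Smo* over WT unless stated otherwise. Values are means ± SD over 3 libraries, and SE is limma's moderated standard error. The difference between ages was tested per gene as a z value from the 2 separate fits with a two-sided normal p. The SE given with such a difference combines the SEs of those 2 fits. Because this test was liberal on simulated data, an interaction term from 1 limma fit of all 12 libraries was added after the data had been seen. P28 against P20 within each genotype was tested in that same fit, also added then, because the values were normalized together.

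A total of 34 gene lists were fixed before the data were examined, along with the tests, the alternatives and the rule for named genes. The lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry, whose p tests whether a list's genes move on balance one way. For each list the text gives how many tested members rose and fell with adjustment over all genes tested, and then adjusted over the list alone. Genes named per comparison were Smo, Gli1, Ptch1 and Hhip, the 10 largest changes in each direction among called genes with a mean of at least 50, an ordinary gene symbol and no overlap between the 2 groups, up to 4 members of each list by adjusted p, and the 5 largest differences between ages in each direction. Stage comparisons follow the same rule of largest changes. Some genes that the rule names are not reported here.

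Alternatives were TMM scaling, quantile normalization, scaling without mitochondrial and the top 10 genes, no filter, a mean of at least 50, pseudocounts of 0.5 and 5, no variance trend, robust empirical Bayes, edgeR 4.0.16 (quasi-likelihood) on the recovered reads, the authors' own adjusted p-values, other thresholds and leaving out each library. DESeq2 1.42.0 on the recovered reads, limma on all 12 libraries, removal of trends with GC content and length, thinning to the smallest library and a replicate block of Smo* and WT libraries with the nearest title numbers were added after the data had been seen. Every library held at least 36323058 reads on genes, and intervals given for read counts cover counting error only. With 3 libraries against 3, an exact permutation test of a single value cannot go below p = 0.1.

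The tests were tested on simulated counts with the real means and depths. At P20 (14504 genes) 50.0% of 100 genes changed by 1 on the log2 scale and 87.6% of 97 changed by 2 were called, and 7.53% of the calls were unchanged genes. At P28 (14569 genes) these shares were 42.9% of 98, 85.9% of 99 and 9.29%. For the difference between ages (14102 genes, 187 changed by each amount) the z test recovered 44.9% and 86.1% with 22.7% of calls unchanged, and the interaction term recovered 25.7% and 76.5% with 4.41% unchanged. For the stage comparison in WT (14790 genes, 100 changed by each amount) the shares were 59.0%, 86.0% and 6.45%. In simulated data with no list shifted, 0 of 34 lists were called by camera at either age. The simulated genes varied independently, so this could not show false list calls from genes that vary together. In the real data, splits of the libraries that mix the genotypes called up to 11 lists at P20 and 13 at P28.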

Results

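RNA of dermal papilla cells, the mesenchymal cells at the base of the hair follicle, was sequenced from WT mice and from Smo* mice, which carry a gain-of-function form of Smo in these cells. Smo is the membrane protein that passes the Hedgehog signal into the cell. At P20, 3 WT and 3 Smo* libraries were labelled female and telogen, the resting stage of the hair cycle. At P28, 3 WT libraries were labelled male and anagen VI, and 3 Smo* libraries male and anagen I-III, so genotype and growth stage differ together at that age. No label states that libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

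The libraries held 36323058 to 48926831 reads on genes, with 39428285 to 47443932 at P20. The lowest and the highest were both at P28. Between 17337 and 17926 genes had a read, except in P28 Smo* replicate 3, which had 15453. This library also had the lowest Spearman correlations across genes with its replicates, at 0.968 and 0.964, against 0.981 or more for every other replicate pair. Replicate pairs differed by more than sampling noise, with a chi-square per gene of 38.5 to 156. Xist, the RNA of the inactive X chromosome, lay at 18899 to 35023 normalized counts at P20 and at 0 to 63.1 at P28. The Y-linked gene Ddx3y lay at 0 to 2.07 and 2173 to 3060, as the labelled sexes require. Col1a1, Col1a2 and Col3a1, the main fibrillar collagen chains, took 36.9% ± 0.662 of reads in P20 WT and 31.4% ± 0.802 in P20 Smo* (SD, n = 3). At P28 they took 30.0% ± 4.02 in WT and 39.6% ± 4.19 in Smo*.

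The first comparison asked which transcripts differ between Smo* and WT cells in telogen. Of 14 Hedgehog target genes, 6 were higher in Smo* cells and 8 did not pass the test. Hhip, a membrane protein that binds Hedgehog ligands, rose from 1229 ± 262 to 14014 ± 694 normalized counts (log2 fold change 3.53, SE 0.15, limma adjusted p = 9.28e-05). Ptch1, the Hedgehog receptor, rose from 4324 ± 1670.1 to 31268 ± 11633 (log2 fold change 2.87, SE 0.36, limma adjusted p = 0.0179). Gli1, a transcription factor of the pathway, rose from 1515 ± 645 to 4477 ± 829.9 (log2 fold change 1.63, SE 0.27, limma adjusted p = 0.0449). Smo itself lay at 5099.8 ± 108 in WT and 7074 ± 633 in Smo* (log2 fold change 0.47, SE 0.10, limma adjusted p = 0.111), a difference that did not pass the test. Reads of the added and the endogenous copy were not told apart.

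The identifiers and GRCm38 positions of these genes were ENSMUSG00000001761 (chromosome 6, 29735503 to 29761365) for Smo, ENSMUSG00000025407 (chromosome 10, 127329882 to 127341974) for Gli1, ENSMUSG00000021466 (chromosome 13, 63508328 to 63573598) for Ptch1 and ENSMUSG00000064325 (chromosome 8, 79965851 to 80058006) for Hhip. The Gli1 call at P20 rested on single libraries: without Smo* replicate 1, 2 or 3 its limma adjusted p was 0.0884, 0.121 and 0.0789, and without WT replicate 1 or 2 it was 0.124 and 0.144. With 1 library left out the fold change of Gli1 lay between 1.39 and 1.95 on the log2 scale, and the call held without WT replicate 3. The Ptch1 call ended without Smo* replicate 2 and without WT replicate 2.

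**Figure D1:**
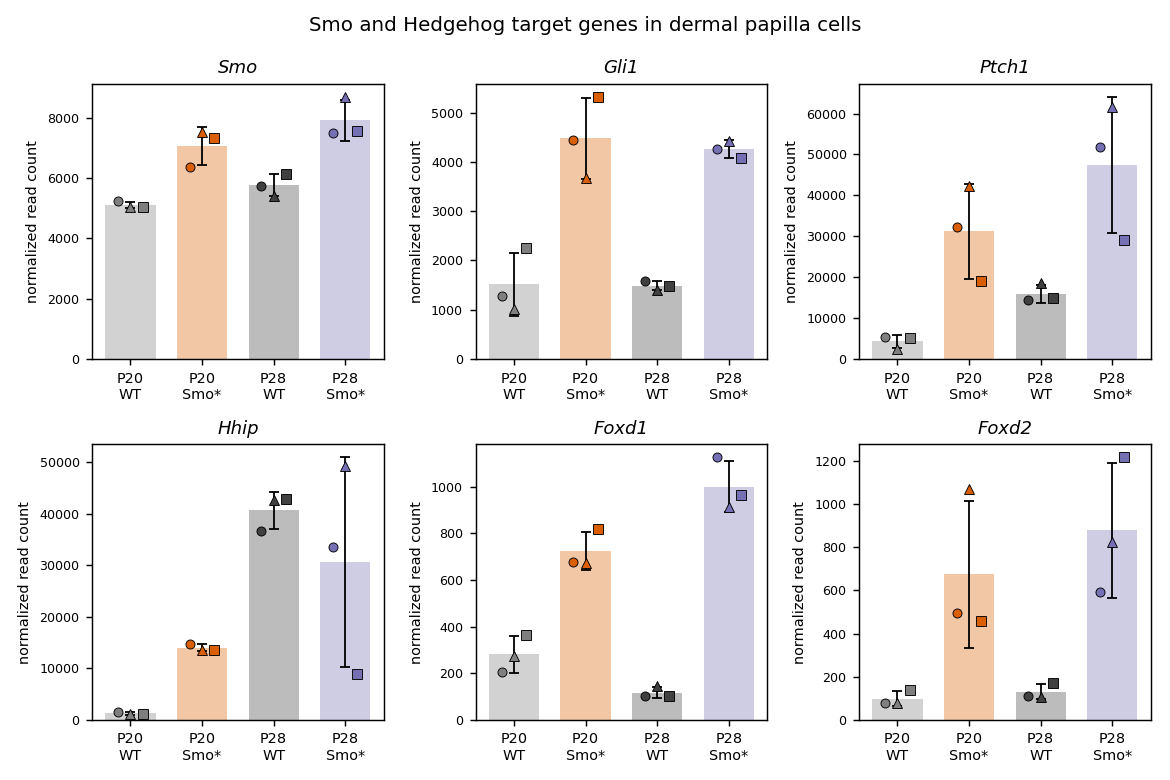
Normalized read counts of Smo and 5 Hedgehog target genes in the 4 groups, with bars at the mean, error bars showing the SD and points for the 3 libraries of a group. Gli1 lay at 1515 in WT and 4477 in Smo* at P20, and at 1487 and 4259 at P28, while Hhip lay at 40696 in WT and 30588 in Smo* at P28, with Smo* replicate 3 at 8915.

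The largest increase at P20 was in Grin2a, a subunit of the NMDA receptor (5.01 on the log2 scale, from 4.10 ± 1.46 to 212 ± 152). It was followed by Clic6, an intracellular chloride channel protein (4.72, from 21.4 ± 5.88 to 590.4 ± 162), and, after Hhip, by Adamts18, a secreted metalloproteinase (3.44). Arhgap8 rose as well (3.35). Iyd, which recovers iodide from iodotyrosines (3.21), the transcription factor Sox18 (3.14, from 369.6 ± 204 to 3334 ± 2055), the O-glycosylation enzyme Galnt3 (3.00) and the transmembrane protein Dner (2.89) also rose. Decreases were largest in the glutamate receptor Grm4 (-3.67), the peroxide-producing oxidase Duox2 (-3.64), the secreted glycoprotein Stc2 (-3.06, from 4009.5 ± 1753 to 492 ± 253), the secreted protein Crispld1 (-2.63) and the adhesion molecule Ncam2 (-2.41). Akr1c18, a steroid dehydrogenase (-2.02), the proteoglycan Spock1 (-1.96), the lipase Pnpla3 (-1.86), Lurap1l (-1.80) and the guanine nucleotide exchange factor Mcf2l (-1.71) fell as well. Beside Hhip, limma adjusted p for these genes ran from 0.000815 for Clic6 to 0.0476 for Duox2.

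Among the lists fixed beforehand, of Hedgehog target genes 6 rose and 0 fell of 14 (adjusted over the list alone, 7 and 0) at P20. They included the forkhead transcription factors Foxd2 (2.72) and Foxd1 (1.40). The list was called up (camera adjusted p = 9.45e-06, adjusted p = 0.180 with an estimated correlation), and by fry at adjusted p = 0.00487. Of the dermal papilla signature, 5 rose and 1 fell of 35 (adjusted over the list alone, 15 and 5), and the list was called up (camera adjusted p = 0.00415, adjusted p = 0.520 with an estimated correlation). Sox18, the secreted Wnt antagonist Frzb (1.45) and Foxd1 were among the higher, and the matrix protein Spon1 (-0.91) was lower. With 1 library left out at a time, the Spon1 call ended for 6 libraries, those of Frzb and Foxd1 for 5 each and that of Sox18 for 3. Frzb and Spon1 also lost the call in the authors' deposited table. Of Hedgehog ligands, receptors and regulators, 1 rose and 0 fell of 15 (adjusted over the list alone, 3 and 2, camera adjusted p = 0.383). The gene that rose was Scube3, a secreted protein that helps release Hedgehog (1.90). The Scube3 call ended in 9 of 23 settings, among them 5 with a library left out and limma on 12 libraries. Of secreted Wnt inhibitors, 2 rose and 0 fell of 13 (adjusted over the list alone, 6 and 5, camera adjusted p = 0.327), namely Frzb and Igfbp4, an IGF-binding protein (2.62, from 5877 ± 1439 to 35674 ± 5056). Igfbp4 was also the gene of the FGF and IGF list, of which 1 rose and 0 fell of 25 (adjusted over the list alone, 2 and 2, camera adjusted p = 0.193).

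Cell cycle genes were called up as a list although 0 passed of 33 (adjusted over the list alone, 1 and 0, camera adjusted p = 3.80e-06, adjusted p = 0.601 with an estimated correlation), with a median log2 fold change of 0.60. Among lists called down were immediate early and dissociation genes, of which 0 passed of 21 (adjusted over the list alone, 0 and 0, camera adjusted p = 3.80e-06, adjusted p = 0.361 with an estimated correlation). Cytosolic ribosomal protein genes were also called down, and 0 passed of 33 (adjusted over the list alone, 0 and 0, camera adjusted p = 0.000642, adjusted p = 0.601 with an estimated correlation). Fibrillar and other collagens were also called down, and 1 rose and 0 fell of 22 (adjusted over the list alone, 1 and 2, camera adjusted p = 0.00280, adjusted p = 0.561 with an estimated correlation). The gene that rose was Col12a1 (0.79). Its call ended in 11 of 23 settings, among them 5 with a library left out, edgeR and the replicate block. So were TGF-beta and activin genes, of which 0 passed of 16 (adjusted over the list alone, 0 and 2, camera adjusted p = 0.00415, adjusted p = 0.520 with an estimated correlation). Proteoglycans and glycoproteins of the matrix, of which 0 rose and 1 fell of 31 (adjusted over the list alone, 2 and 5), were called down too (camera adjusted p = 0.00965, adjusted p = 0.520 with an estimated correlation). Interferon-stimulated genes, of which 0 passed of 17 (adjusted over the list alone, 0 and 0), were called down (camera adjusted p = 0.00893, adjusted p = 0.601 with an estimated correlation). With quantile normalization the calls of the collagen, matrix, ribosomal protein and TGF-beta lists ended (camera adjusted p = 0.925, 0.827, 0.858 and 0.0769). The matrix call also ended without WT replicate 3 (0.0622), the interferon call without Smo* replicate 2 (0.101) and the ribosomal protein call without Smo* replicate 1 (0.0559).

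Among markers of other cell types at P20, dermal fibroblast markers were called down, and 0 rose and 1 fell of 13 (adjusted over the list alone, 1 and 9, camera adjusted p = 4.99e-06, adjusted p = 0.180 with an estimated correlation, fry adjusted p = 0.00863). The gene that fell was Dpt, a matrix protein of the dermis, from 26078 ± 1130.4 to 14958 ± 318 (-0.80). Of dermal sheath and smooth muscle markers 1 rose and 0 fell of 13 (adjusted over the list alone, 1 and 0, camera adjusted p = 0.559). The gene was Myocd, a coactivator of smooth muscle genes (1.84), while 11 of the 13 lay below 0 (median -0.26) and camera and fry pointed down. Keratinocyte markers of the basal layer and outer root sheath were called down, and 0 passed of 15 (adjusted over the list alone, 0 and 0, camera adjusted p = 0.0128, adjusted p = 0.601 with an estimated correlation). Immune cell markers were called down too, and 0 passed of 13 (adjusted over the list alone, 0 and 0, camera adjusted p = 0.0250, adjusted p = 0.674 with an estimated correlation). The keratinocyte call ended with no filter (camera adjusted p = 0.121), with a mean of at least 50 (0.207), without Smo* replicate 2 (0.0899) and without WT replicate 3 (0.200). The immune call ended with a mean of at least 50 (0.435) and without Smo* replicate 2 (0.456), Smo* replicate 3 (0.106) or WT replicate 2 (0.475). Skeletal muscle markers were called up, and 0 passed of 6 (adjusted over the list alone, 1 and 0, camera adjusted p = 0.00415, adjusted p = 0.327 with an estimated correlation). That call ended with no filter (0.0546), and fry did not call the list (0.0853).

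Lists that camera did not call at P20 are given with their counts in the same form. Of ligands linked to the telogen-anagen switch 0 passed of 20 (adjusted over the list alone, 3 and 4, camera adjusted p = 0.525). Of Wnt/beta-catenin target genes 0 passed of 17 (adjusted over the list alone, 1 and 3, camera adjusted p = 0.707). Of BMP pathway genes 0 passed of 24 (adjusted over the list alone, 0 and 4, camera adjusted p = 0.170). Notch pathway genes had camera adjusted p = 0.193, and 0 passed of 14 (adjusted over the list alone, 4 and 1). Of axon guidance ligands 0 passed of 22 (adjusted over the list alone, 3 and 2, camera adjusted p = 0.560). For endothelial markers, 0 passed of 13 (adjusted over the list alone, 2 and 1, camera adjusted p = 0.239). For Schwann cell markers, 0 passed of 8 (adjusted over the list alone, 0 and 1, camera adjusted p = 0.642). For erythroid markers, 0 passed of 2 (adjusted over the list alone, 0 and 1, camera adjusted p = 0.283). The median of the ligand list (-0.07) and its test lay below 0 and its mean (0.02) above. The median of the Wnt target list (0.01) lay above 0 with its mean (-0.14) and test below. The FGF and IGF list had a median of -0.21 and a test below 0 with a mean of 0.03. The remaining lists had no call either over all genes or adjusted over the list alone. They were retinoid genes (13 tested, camera adjusted p = 0.822), cholesterol synthesis genes (20, camera adjusted p = 0.327), glycolysis and hypoxia genes (19, camera adjusted p = 0.327), and pericyte markers (9, camera adjusted p = 0.222). They also included hair matrix, inner root sheath and shaft markers (5, camera adjusted p = 0.410), melanocyte markers (5, camera adjusted p = 0.383), adipocyte markers (9, camera adjusted p = 0.217), mitochondrially encoded genes (13, camera adjusted p = 0.822) and X and Y chromosome sex genes (3, camera adjusted p = 0.265). Some lists without a call gained one in the same direction in other settings. Without Smo* replicate 2 these were cholesterol synthesis genes (camera adjusted p = 3.05e-05), adipocyte (1.50e-05) and erythroid markers (0.0372), and without Smo* replicate 3 FGF and IGF genes (0.0265). Without WT replicate 1 they were endothelial (0.00199), dermal sheath (0.0207) and pericyte markers (0.0420), and without WT replicate 3 Notch pathway genes (0.0207). Without WT replicate 2 they were cholesterol synthesis (0.0169), FGF and IGF (0.0355) and Wnt target genes (0.0435) and erythroid markers (0.0355), which were also called with no filter (0.00762). With pairs of nearest title numbers as a block they were endothelial (0.0280) and adipocyte markers (0.00506). In the 25 lists with 0 members called by limma over all genes, 78 of 360 different genes had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 26.

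In all, limma called 102 of 14645 genes at P20, 71 higher and 31 lower in Smo*. A total of 86 changed by at least 2-fold. The 3 Smo* and 3 WT values did not overlap in 16.4% of tested genes, where chance gives 10% on average over splits of the libraries. Because genes vary together, single splits can lie away from that average, and their spread in this share was not computed. The authors' deposited table calls 342 genes at the same threshold, 223 higher and 119 lower in Smo*, and 92 of the 102 are among them in the same direction. The count fell to 8 without WT replicate 2, 19 without Smo* replicate 2 and 42 without WT replicate 1. Without Smo* replicate 1 it was 129, with 31.8% higher. With Smo* and WT libraries of neighbouring title numbers joined in a replicate block it was 239, 129 higher and 110 lower. Of the 33 named genes called, Adamts18, Clic6, Crispld1, Hhip, Igfbp4 and Iyd passed with each library left out. By contrast, 27 lost the call without WT replicate 2, 23 without Smo* replicate 2, 16 without WT replicate 1, 15 without Smo* replicate 1, 11 without WT replicate 3 and 5 without Smo* replicate 3.

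At P28 the question was the same in anagen, with WT labelled at a later stage than Smo*. Corin, a serine protease and marker of the dermal papilla, fell from 73141 ± 5785 to 4252 ± 3554 normalized counts (log2 fold change -4.65, SE 0.72, limma adjusted p = 0.00795). Rspo4, a secreted enhancer of Wnt signalling, fell from 37714 ± 2151 to 1054 ± 944 (log2 fold change -5.54, SE 0.52, limma adjusted p = 0.000803). Inhba, the activin A subunit, fell from 14890.1 ± 1130.2 to 1599 ± 822 (log2 fold change -3.39, SE 0.40, limma adjusted p = 0.00219). Gli1 rose from 1487 ± 93.0 to 4259 ± 182 (log2 fold change 1.52, SE 0.11, limma adjusted p = 0.000237). Ptch1 rose from 16005 ± 2206 to 47449 ± 16659 (log2 fold change 1.51, SE 0.28, limma adjusted p = 0.0152). Hhip lay at 40696 ± 3544 in WT and 30588 ± 20379 in Smo* (log2 fold change -0.73, SE 0.55, limma adjusted p = 0.430). Smo lay at 5762 ± 364 and 7911 ± 679 (log2 fold change 0.46, SE 0.12, limma adjusted p = 0.0502), and neither gene passed the test. The Hhip change came from Smo* replicate 3 (at 8915), without which its log2 fold change was 0.0024 (limma adjusted p = 0.996). Without Smo* replicate 3, Smo passed it (log2 fold change 0.49, limma adjusted p = 0.0481). Without WT replicate 1, 2 or 3 the Ptch1 call was lost.

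**Figure D2:**
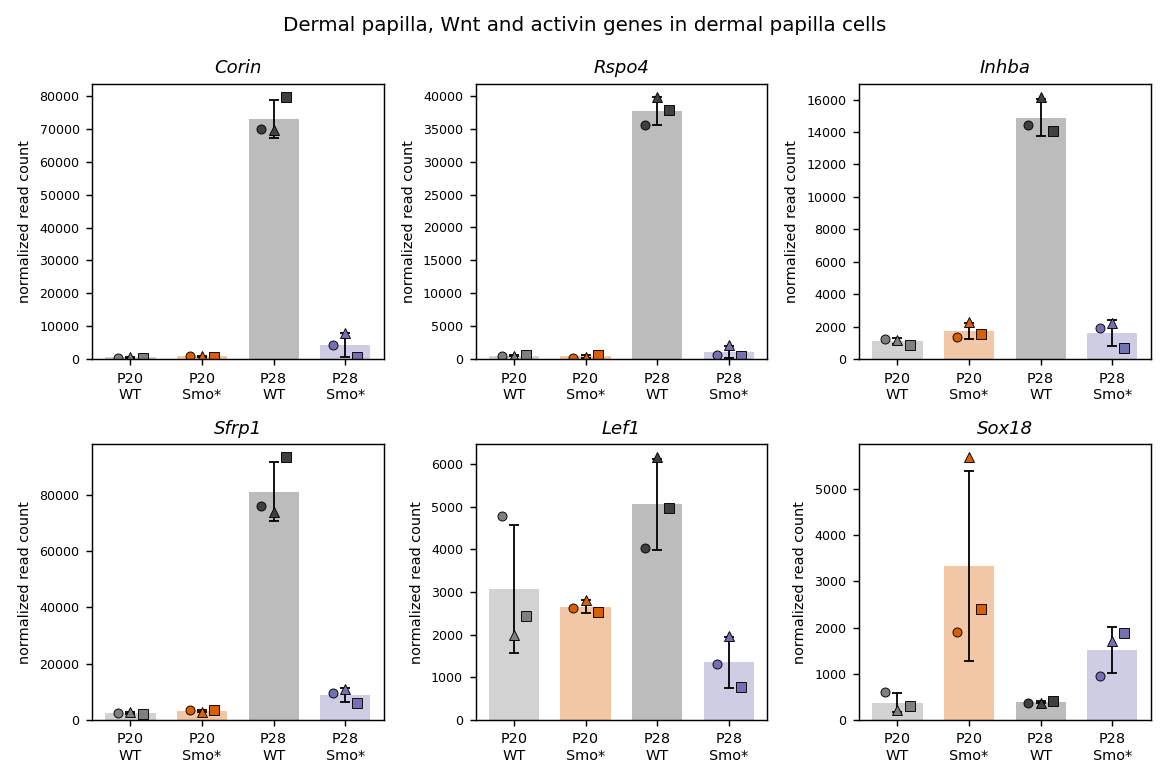
Normalized read counts of 6 dermal papilla, Wnt and activin genes in the 4 groups, with bars at the mean, error bars showing the SD and points for the 3 libraries of a group. Corin lay at 546 in P20 WT, 847 in P20 Smo*, 73141 in P28 WT and 4252 in P28 Smo*.

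The largest increases at P28 were in Adamdec1, a metalloprotease (6.88 on the log2 scale), Msln, a surface glycoprotein (6.31), the organic anion transporter Slco4c1 (5.69), Msantd1 (5.62) and Rab3b, a GTPase of vesicle release (5.60). Iyd (5.06, from 11.5 to 356 on average), the Rac GTPase-activating protein Chn2 (4.89), Shisa3 (4.74, from 33.5 ± 11.3 to 913 ± 286), Vat1l (4.63) and the adhesion protein Mpzl2 (4.58) followed. Adamdec1 had 2 reads in the WT libraries together and 985 in Smo*, a ratio of normalized totals of 527 with an exact 95% interval of 145 to 4358. The largest decreases besides Rspo4 were in the neuropeptide precursor Npvf (-6.78), Amph, a protein of endocytosis (-6.64), the nucleotide receptor P2ry6 (-6.31), the galactolipid synthase Ugt8a (-6.27, from 739.7 ± 145 to 18.8 ± 16.5) and the neuropeptide FF receptor Npffr2 (-6.07, from 820.5 ± 16.8 to 28.2 ± 25.2). Dcdc2a (-5.76), the acute-phase protein Orm1 (-5.72), the kininogen Kng2 (-5.69) and the potassium channel partner Kcnip4 (-5.56) fell too. Npvf had 449 reads in WT and 1 in Smo*, a ratio of normalized totals of 420 with an exact 95% interval of 74.9 to 16611. Limma adjusted p for these genes ran from 0.000281 for Shisa3 to 0.0464 for Rab3b, and Rab3b lost its call without Smo* replicate 1 or 2 and without each WT library. Amph lost it without Smo* replicate 1 and each WT library, Npffr2 without each WT library, Adamdec1 without Smo* replicate 1, WT replicate 1 or WT replicate 3, Ugt8a and Kng2 without WT replicate 2 or 3, and Orm1 without WT replicate 3 and in the authors' deposited table. All of these except Orm1 also lost it without a variance trend.

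Of Hedgehog target genes 8 rose and 1 fell of 14 (adjusted over the list alone, 10 and 2) at P28, with Foxd1 (3.12) and Foxd2 (2.73) among the higher. Sfrp1, a secreted Wnt inhibitor, fell from 81196 ± 10562 to 8750.4 ± 2554 (-3.25). The list was called up (camera adjusted p = 0.000116, adjusted p = 0.298 with an estimated correlation), and by fry at adjusted p = 0.000749. Of the dermal papilla signature 2 rose and 11 fell of 35 (adjusted over the list alone, 2 and 17), and the list was called down (camera adjusted p = 0.00748, adjusted p = 0.802 with an estimated correlation). Its call was lost without the genes that other lists share (camera adjusted p = 0.447). Foxd1 and Sox18 (1.93) were the members that rose. Of Hedgehog ligands, receptors and regulators 1 rose and 2 fell of 15 (adjusted over the list alone, 4 and 3, camera adjusted p = 0.705). The co-receptor Cdon (1.27) rose, and the secreted protein Scube1 (-3.35) and the repressor Gli3 (-0.63) fell. The median (-0.04) and mean (-0.22) of that list lay below 0 and its camera and fry directions were up.

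At P28 each of the following signalling lists had members called in both directions, and camera in the main setting did not call these lists. Of ligands linked to the telogen-anagen switch 3 rose and 6 fell of 20 (adjusted over the list alone, 4 and 9, camera adjusted p = 0.104). Rspo4, Inhba, the BMP ligand Bmp2 (-1.69) and the BMP antagonist Nog (-2.75) were lower. Of Wnt/beta-catenin target genes 1 rose and 6 fell of 17 (adjusted over the list alone, 3 and 8, camera adjusted p = 0.104, fry adjusted p = 0.0261). The transcription factor Lef1 (-1.99) and the feedback inhibitors Axin2 (-1.46) and Apcdd1 (-1.39) were lower. Of secreted Wnt inhibitors 3 rose and 3 fell of 13 (adjusted over the list alone, 5 and 6, camera adjusted p = 0.792). Sfrp5 (4.37) and Sost (4.73) were higher and Sfrp1 and Dkk2 (-0.91) lower. The median (-0.91), mean (-0.12) and camera direction of that list were down, and fry's was up. Without genes in more than 1 list its direction reversed and it was called up (camera adjusted p = 0.0490). BMP pathway genes had camera adjusted p = 0.276, and 1 rose and 5 fell of 24 (adjusted over the list alone, 2 and 6), Bmp3 (-1.64) and the pseudoreceptor Bambi (-2.27) being lower. For TGF-beta and activin genes, 1 rose and 3 fell of 16 (adjusted over the list alone, 2 and 5, camera adjusted p = 0.129). The matrix protein Tgfbi (1.03) rose and Tgfb1 (-0.63) and Inhbb (-1.12) fell. The Tgfbi call ended in 10 of 23 settings, that of Tgfb1 in 5 and that of Inhbb in 4. Of FGF and IGF genes 4 rose and 6 fell of 25 (adjusted over the list alone, 4 and 10, camera adjusted p = 0.194). The FGF feedback inhibitors Spry1 (-2.60, from 14042 ± 1412 to 2333 ± 380.1) and Spry4 (-2.38), the FGF-induced factor Etv5 (-1.77) and the receptor Fgfr3 (-1.70) were lower.

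Of Notch pathway genes 5 rose and 1 fell of 14 (adjusted over the list alone, 5 and 1) at P28 (camera adjusted p = 0.0688). The ligand Dll1 (2.39), Heyl (1.09) and Notch1 (0.91) rose and Notch4 (-3.55) fell. Retinoid genes had camera adjusted p = 0.924, and 3 rose and 2 fell of 13 (adjusted over the list alone, 3 and 4). The retinol receptor Stra6 (2.58) and carrier Rbp4 (1.12) were higher and Crabp1 (-2.58) lower. Cell cycle genes were called up (camera adjusted p = 2.43e-07, adjusted p = 0.802 with an estimated correlation), and 4 rose and 0 fell of 33 (adjusted over the list alone, 8 and 0). They were the replication genes Mcm4 (1.03), Mcm2 (1.45) and Pcna (0.71) and the transcription factor E2f1 (0.64). Each of them lost the call without WT replicate 2, without WT replicate 3 and without a variance trend. Cholesterol synthesis genes were called up (camera adjusted p = 0.000993, adjusted p = 0.802 with an estimated correlation), and 4 rose and 0 fell of 20 (adjusted over the list alone, 8 and 0). The enzymes Idi1 (1.20), Cyp51 (0.93) and Hmgcs1 (0.85) and the pathway's regulator Insig1 (0.90) were higher. All of these also lost the call without WT replicate 2, without WT replicate 3 and without a variance trend. With single libraries left out, the Hmgcs1 call ended for 5 of them and the Cyp51 call for 4. For fibrillar and other collagens, 5 rose and 2 fell of 22 (adjusted over the list alone, 6 and 2, camera adjusted p = 0.104), with Col4a6 (1.63) higher and Col13a1 (-2.70) lower. For matrix proteoglycans and glycoproteins, 4 rose and 3 fell of 31 (adjusted over the list alone, 4 and 3, camera adjusted p = 0.439). Postn (1.13) and Fbln2 (0.90) were higher and Spon1 (-2.41) lower. Of axon guidance ligands 4 rose and 2 fell of 23 (adjusted over the list alone, 6 and 2, camera adjusted p = 0.104), Sema3a (0.87), Sema6a (0.87) and Ntn1 (0.96) rising. Of glycolysis and hypoxia genes 1 rose and 1 fell of 19 (adjusted over the list alone, 1 and 1, camera adjusted p = 0.612). The glucose transporter Slc2a1 (1.03) rose and Ndrg1 (-1.14) fell. The Ndrg1 call ended in 8 of 23 settings, edgeR among them. For the retinoid and the glycolysis list the medians (-0.16 and -0.0039) lay below 0 and the means (0.07 and 0.10) and tests above.

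Among markers of other cell types at P28, the endothelial list was called up, and 4 rose and 0 fell of 14 (adjusted over the list alone, 8 and 1, camera adjusted p = 0.000326, adjusted p = 0.640 with an estimated correlation). The junction protein Cdh5 rose from 94.1 ± 54.4 to 1817 ± 608 (4.37), along with Flt1 (2.18), Vwf (1.93) and Pecam1 (1.53, to 275 ± 83.3). Dermal fibroblast markers had camera adjusted p = 0.940, and 1 rose and 3 fell of 13 (adjusted over the list alone, 2 and 3). Dlk1 (1.31) was higher and Sfrp2 (-1.18), Pdgfra (-0.57) and Gpx3 (-0.88) lower, with a median of 0.04, a mean of -0.01 and tests pointing down. When single libraries were left out, the Pdgfra call ended for 6 of them, those of Dlk1 and Gpx3 for 5 each and that of Sfrp2 for 2. Of keratinocyte markers 2 rose and 0 fell of 17 (adjusted over the list alone, 2 and 1, camera adjusted p = 0.155). The integrin Itga6 (1.32) and the R-spondin receptor Lgr5 (1.23) rose, while 13 of the 17 had fold changes below 0 (median -0.78, mean -0.91) and camera and fry pointed down. For hair matrix, inner root sheath and shaft markers, 0 rose and 2 fell of 8 (adjusted over the list alone, 0 and 4, camera adjusted p = 0.0869, fry adjusted p = 0.0437). They were Crym (-4.66) and Krt71, which had 1 read in Smo*. Of dermal sheath and smooth muscle markers 2 rose and 1 fell of 13 (adjusted over the list alone, 2 and 2, camera adjusted p = 0.439). Cnn1 (1.21) and Mylk (0.79) were higher and Itga8 (-1.56) lower. The Cnn1 call ended in 7 of 23 settings and that of Mylk in 4. Of pericyte markers 0 rose and 1 fell of 9 (adjusted over the list alone, 1 and 1, camera adjusted p = 0.286), the gene being Rgs5 (-0.65), while 7 of the 9 lay above 0 (median 0.26) and camera and fry pointed up. The Rgs5 call was lost in 11 of 23 settings, the authors' deposited table among them. Kcnj8 and Abcc9, singled out after their values were seen, were called higher in Smo* in that table (deposited adjusted p = 0.00852 and 0.0222). Of Schwann cell markers 0 rose and 1 fell of 7 (adjusted over the list alone, 1 and 1, camera adjusted p = 0.439), the gene being Cdh19 (-3.37), while 5 of the 7 lay above 0 (median 0.31) and camera and fry pointed up.

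Mitochondrially encoded genes were called down at P28, and 0 rose and 1 fell of 13 (adjusted over the list alone, 0 and 9, camera adjusted p = 0.00140, adjusted p = 0.802 with an estimated correlation), the gene being mt-Cytb (-0.97). They took 0.958% ± 0.305 of reads in P28 WT and 0.472% ± 0.0409 in P28 Smo* (SD, n = 3). The mt-Cytb call was lost in 10 of 22 settings, among them 5 with a library left out and quantile normalization. Of immediate early and dissociation genes 2 rose and 0 fell of 21 (adjusted over the list alone, 2 and 0, camera adjusted p = 0.350), the transcription factors Egr3 (3.46) and Nr4a1 (1.52). The other lists had no call over all genes or adjusted over the list alone: interferon-stimulated genes (18 tested, camera adjusted p = 0.483), melanocyte markers (7, camera adjusted p = 0.747), immune cell markers (12, camera adjusted p = 0.826), adipocyte markers (9, camera adjusted p = 0.0869), skeletal muscle markers (6, camera adjusted p = 0.439), erythroid markers (5, camera adjusted p = 0.454), cytosolic ribosomal protein genes (33, camera adjusted p = 0.511) and X and Y chromosome sex genes (5, camera adjusted p = 0.481). Some lists without a call at P28 gained one in the same direction in other settings. With a mean of at least 50 these were the ligands of the telogen-anagen switch (camera adjusted p = 0.00821), Wnt targets (0.0407) and FGF and IGF genes (0.0421). With no filter they were hair matrix (0.0118) and adipocyte markers (0.0276), Notch pathway genes (0.0276), collagens (0.0444) and axon guidance ligands (0.0495). Without Smo* replicate 3 they were Notch pathway genes (0.0201), immediate early genes (0.0342) and the ligands (0.0416), and without Smo* replicate 2 adipocyte markers (0.000909) and the ligands (0.0375). Ribosomal protein genes were called without Smo* replicate 1 (0.0314), collagens without WT replicate 1 (0.0308), and hair matrix markers (0.0425), TGF-beta genes and keratinocyte markers (0.0478 each) without WT replicate 3. In the 8 lists without a call over all genes or over the list alone, with 0 members called by limma, 12 of 95 different genes had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 2.

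In all, limma called 1313 of 14757 genes at P28, 597 higher and 716 lower in Smo*, 786 of them by at least 2-fold. Smo* and WT values did not overlap in 33.4% of tested genes, where chance gives 10% on average over splits, with a spread that was not computed. The authors' deposited table calls 2880 genes, 1446 higher and 1434 lower in Smo*, and 1276 of the 1313 are among them in the same direction. The count fell to 461 without WT replicate 3, 472 without WT replicate 2, 795 without WT replicate 1 and 852 without Smo* replicate 1. It was 1619 (810 higher) without Smo* replicate 3, the library that stands apart. Of the 104 named genes called, 49 passed in every setting tried, among them Corin, Rspo4, Inhba, Gli1, Foxd1, Sfrp1, Spry1 and Cdh5. Genes named above without a remark on lost calls are not all among these 49. A total of 48 lost the call without WT replicate 2, 48 without WT replicate 3, 29 without WT replicate 1, 26 without Smo* replicate 1, 15 without Smo* replicate 2 and 7 without Smo* replicate 3. With an estimated correlation camera called 0 lists at P20 and 0 at P28 (smallest adjusted p = 0.180 and 0.298). At these ages 4 and 1 lists had an unadjusted p under 0.05 with it, camera with the preset correlation called 13 and 6 lists, and fry called 2 and 3.

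The effect of Smo* was then compared between ages, which also differ in sex and in the stage gap between genotypes. Each SE of a difference given here combines the SEs of the 2 separate fits, as in the z test, and is not that of the interaction term. Corin showed one of the largest differences: its effect was 0.67 at P20 and -4.65 at P28 (difference -5.32, SE 0.76, interaction adjusted p = 0.00581 by limma). Galnt3 went from 3.00 to -2.49 (difference -5.49) and the phosphatase Dusp4 from 0.82 to -4.32 (difference -5.14). Among positive differences, the hormone Fgf23 went from -1.46 to 3.95 (difference 5.42) and the chemokine Ccl2 from -1.49 to 2.18 (difference 3.67). The drug efflux pump Abcb1a went from -1.44 to 2.17 (difference 3.62) and Spock1 from -1.96 to 1.63 (difference 3.59). At P20 the effects of Fgf23, Ccl2 and Abcb1a, like those of Corin and Dusp4, did not pass the test. The P28 call of Abcb1a was lost with each library left out in turn. Hhip differed by -4.26 (SE 0.57, interaction adjusted p = 0.00359 by limma), and by -3.53 (interaction adjusted p = 8.25e-05) without P28 Smo* replicate 3. Gli1 differed by -0.11 (SE 0.29) and Ptch1 by -1.36 (SE 0.45), neither called by the interaction term (adjusted p = 0.874 and 0.146), while in the z test Ptch1 passed and Gli1 did not (adjusted p = 0.0256 and 0.853). Without P28 Smo* replicate 3 Ptch1 did not pass the z test either (0.0640). Amph (-6.94), the potassium channel Kcnq3 (-5.66) and Duox2 (4.39) also passed the z test alone.

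The z test called 1987 of 14295 genes, 994 with a more positive and 993 with a more negative effect at P28, and the interaction term called 698 of 14790, 279 and 419. Both called 679 genes. On simulated data 22.7% of the z calls were unchanged genes against 4.41% for the interaction term. Without P28 WT replicate 3 the z test called 1260 genes and the interaction term 254. The interaction term called 309 without P28 WT replicate 2, 329 without P20 WT replicate 2, 400 without P20 Smo* replicate 3, 405 without P20 WT replicate 3, 420 without P20 Smo* replicate 2 and 462 without P28 Smo* replicate 1.

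Among genes tested at both ages, 41 were called in the same direction, 34 higher and 7 lower in Smo* at both, and 9 in opposite directions. Clic6 (4.72 and 3.57), Iyd (3.21 and 5.06), Dner (2.89 and 3.70), Foxd2 (2.72 and 2.73), Ptch1, Gli1 and Sox18 were higher at P20 and at P28. Ncam2 (-2.41 and -3.19), Pnpla3 and Lurap1l were lower. Independent lists would share 2.92 higher and 1.45 lower genes (Fisher's exact test, two-sided p = 1.43e-28 and 0.000464, odds ratios 22.7 and 6.0). This test treats genes as independent, which they are not, and its p does not measure the spread between libraries. The 2 comparisons share no library. The shared count fell to 5 without P20 WT replicate 2, 8 without P20 Smo* replicate 2, 21 without P20 WT replicate 1 and 24 without P20 Smo* replicate 1.

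**Figure D3:**
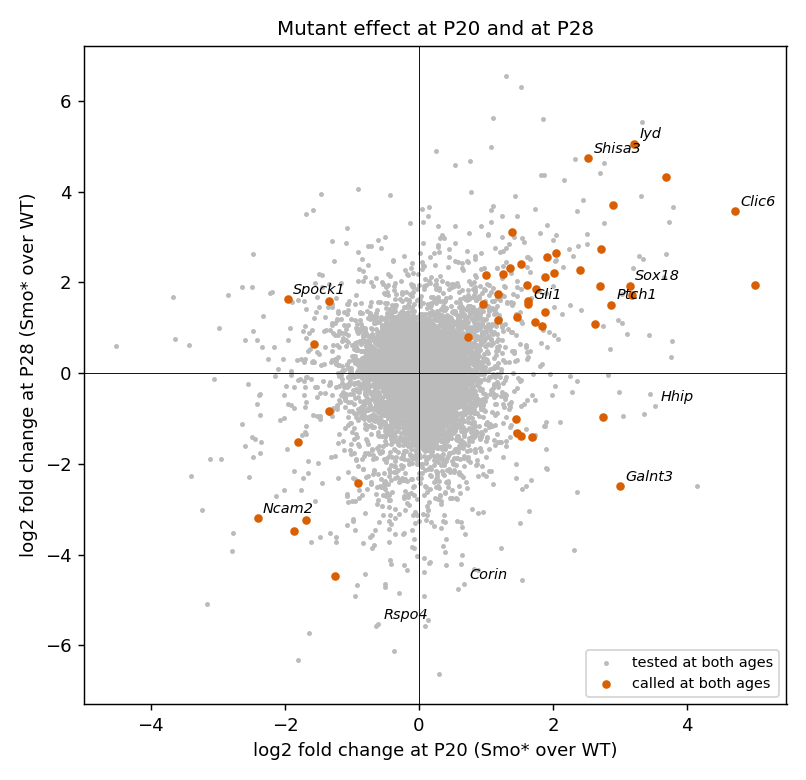
Log2 fold change of Smo* over WT at P20 (x axis) against P28 (y axis) for the 14295 genes tested at both ages, with the genes called at both ages in orange. Clic6 lies at 4.72 and 3.57 and Hhip at 3.53 and -0.73, while Corin lies at 0.67 and -4.65.

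P28 was also compared with P20 within each genotype, where day, sex and stage change together and cannot be told apart. In WT cells, Corin rose from 546 ± 191 to 73141 ± 5785 normalized counts (log2 fold change P28 over P20 7.11, SE 0.61, limma adjusted p = 1.28e-05) and Sfrp1 from 2476 ± 277 to 81196 ± 10562 (5.03, SE 0.20, limma adjusted p = 1.81e-08). Hhip rose from 1229 ± 262 to 40696 ± 3544 (5.06, SE 0.45, limma adjusted p = 1.58e-05). In Smo* cells the Corin and Hhip differences did not pass the test (1.80, SE 0.61, limma adjusted p = 0.112 and 0.81, SE 0.45, limma adjusted p = 0.303), but without P28 Smo* replicate 3 both did (2.77, limma adjusted p = 0.000202, and 1.54, limma adjusted p = 0.000611). Without P28 Smo* replicate 2 they were 1.08 and 0.30. In these cells Sfrp1 rose (1.42, SE 0.20, limma adjusted p = 0.00549). Among the largest WT increases were Ugt8a (8.59), the GABA receptor subunit Gabrg3 (8.28), Kng2 (7.34) and Npffr2 (7.16). Fam196b and the collagen Col9a1 had 3 and 2 reads in P20 WT, against 9723 and 1514 in P28 WT. Among the largest decreases were Sez6l (-7.04), the water channel Aqp5 (-6.39), the Wnt ligand Wnt10a (-6.32), the synuclein Sncb (-5.66) and the glypican Gpc5 (-5.19), besides Xist (-11.53). In Smo* cells the melanocortin receptor Mc3r (5.98), the GABA receptor Gabbr2 (5.23), Tmem215 (4.89), Galnt13 (4.74) and Galnt14 (4.65) were higher at P28. Orm1 (-5.49), the tenascin Tnn (-3.62), Stac (-3.57), the cornified envelope protein Evpl (-3.29), the laminin chain Lama3 (-3.14) and the small GTPase Rasd1 (-3.12) were lower.

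Of the dermal papilla signature, 22 of 35 genes rose and 3 fell from P20 to P28 in WT (median 2.45 on the log2 scale), against 2 and 2 in Smo* (median 0.51). With each library left out in turn, 20 to 22 rose in WT, and 0 rose in Smo* except without P28 Smo* replicate 3, where 15 rose and 2 fell (median 0.99). In all, limma called 3761 of 14790 genes in WT (2000 higher at P28, 1761 lower) and 511 in Smo* (293 and 218). Per gene, the difference between the changes in Smo* and in WT is the interaction term, which called 698 genes. Leaving out P28 WT replicate 3 lowered the WT count to 2336. The Smo* count was 49 without P28 replicate 1, 83 without P20 replicate 3, 178 without P20 replicate 1, 236 without P28 replicate 2 and 1049 without P28 replicate 3.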

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

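The interaction term, the comparison of P28 with P20 within a genotype, the thinning of reads, the comparison of read totals, the removal of GC and length trends, the comparison of other cell type lists and the position of P28 Smo* replicate 3 among the Smo* libraries were tests chosen after the result was seen. Groups of 3 libraries are too small to test for single values far from the others, so the results listed here are differences between ages.

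Of 121 named genes, 54 had a Smo* effect that differed between P28 and P20 in both the z test and the interaction term of limma (threshold 0.05 adjusted). Many named genes were picked for large or significant effects in these same data, so a high share is built in. Over all genes, both tests called 679 of 14295. The difference, P28 minus P20 on the log2 scale, was negative in 28. Among dermal papilla, Hedgehog and Wnt genes these were Corin (-5.32), Rspo4 (-4.93), Hhip (-4.26), Inhba (-4.03), Scube3 (-3.99), Sfrp1 (-3.62), Frzb (-3.45), Nog (-3.00), Bmp3 (-2.25), Lef1 (-1.88), Axin2 (-1.70), Igfbp4 (-1.55) and Apcdd1 (-0.80). Among other signalling genes they were Dusp4 (-5.14), P2ry6 (-4.51), Notch4 (-4.24), Spry1 (-2.39), Spry4 (-2.09), Etv5 (-1.73) and Efna5 (-0.80). The remaining negative differences were in Galnt3 (-5.49), Kcnip4 (-4.91), Crym (-3.73), Cdh19 (-3.59), Adamts18 (-2.59), Myocd (-1.64), Col13a1 (-1.63) and Itga8 (-1.44).

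The difference was positive in 26 of the named genes. Among receptors, ligands and transcription factors these were Fgf23 (5.42), Grm4 (5.35), Ccl2 (3.67), Dll1 (3.15), Egr3 (3.32), Nr4a1 (2.47), Stc2 (2.93), Flt1 (2.35), Foxd1 (1.72) and Sema3a (1.03). Among matrix and adhesion genes they were Msln (4.78), Mpzl2 (4.04), Spock1 (3.59), Vwf (2.62), Col4a6 (1.98), Tgfbi (1.34), Itga6 (1.17), Col16a1 (1.16), Postn (1.02) and Fbln2 (1.0). The rest were Chn2 (4.63), Msantd1 (4.51), Abcb1a (3.62), Shisa3 (2.21), Mcf2l (1.40) and Insig1 (1.18).

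That many genes differ in their Smo* effect between ages was set against other splits of the libraries within each age. Of 100 splits, 1, the real one, called as many genes by the z test (1987, highest other 1804) and 1 by the interaction term (698, highest other 680), but counting splits in this way tests for any genotype effect and not for effects that are unequal between ages. Splits that kept the P28 labels and changed those of P20 still called 1031 to 1804 genes by the z test and 229 to 680 by the interaction term, while the 81 that changed both ages called at most 145 by the z test and 0 by the interaction term of limma (where up to 1143 genes had an unadjusted p under 0.05), so the counts follow the P28 labels, and the 10 splits that keep these labels are too few for a share under 0.05. Genes of the X and Y chromosomes had an odds ratio of 0.897 among the interaction calls (Fisher's exact test, two-sided p = 0.745), which does not bound effects of sex on other genes. Sex, day and the stage gap between genotypes change together between the ages, so they cannot be told apart for these genes.

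The genes lower in Smo* at P28 include 11 of the 35 tested genes of the dermal papilla signature. Removing GC and length trends left 756 lower calls against 716 (677 shared), which argues against those trends as the whole cause. On average the Smo* libraries held no fewer reads than WT (0.11 on the log2 scale, SE 0.13). This argues against a lack of reads in Smo*. The values were already divided by size factors, so this difference cannot be compared with the median of -1.28 for these genes. Thinning to the smallest total (722 lower calls, 698 shared) decides nothing because the Smo* depths lay inside the WT range. If other cell types evenly replaced dermal papilla cells in the Smo* sort, the markers of all of them would rise alike. Instead, the endothelial list (median 1.38, n = 14) lay above the keratinocyte and fibroblast lists together (median -0.50, n = 30) by 1.87. The permutation p = 1e-05 is the smallest the permutations can give, and it treats genes as independent, which they are not. This contrast cannot exclude a lower share made up by 1 or a few cell types. Taken singly, the list medians were 2.49 for adipocyte, 0.04 for fibroblast and -0.78 for keratinocyte markers. Whether endothelial cells added to the rise of Cdh5 stays open. On an axis of 3615 genes called between P20 WT (position 0) and P28 WT (position 1), the P28 Smo* libraries lay at a mean of 0.428 (SD 0.183). On axes each built without 1 P28 WT library, the left-out library lay at 0.886 to 1.04. The mean of the P28 Smo* libraries on these axes was 0.400 to 0.426, and none lay above 0.571. A lag of the mutant in the hair cycle is therefore a candidate explanation, and the stage labels give Smo* the earlier stage. Whether the sampled follicles differed in stage because of Smo* or by the choice of animals was not tested.

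P28 Smo* replicate 3 stands apart from the other Smo* libraries of its age. Its Ddx3y count of 2173, near the lowest of the other P28 libraries (2399), argues against a P20 library under a wrong label. Over the 8 Hedgehog target genes called without this library, it lay a median of 1.94 above the P28 WT mean on the log2 scale. The highest left-out WT library lay at 0.18, which argues against a WT library. Hhip, not called in that fit, was not among these genes. P28 Smo* replicate 3 lay at position 0.225 on the axis from P20 WT to P28 WT, below replicates 1 (0.480) and 2 (0.579). Over abundant genes its position was 0.265, also below the others (lowest 0.380), which argues against a loss of low-abundance transcripts as the whole cause, although it had the fewest genes with a read. An earlier hair cycle position may explain it, as a hypothesis found and tested on the same libraries, but the library also held the most transcripts of adipocyte genes (Cfd at 8165 normalized counts, against 0 to 100.3 in the other P28 libraries), and whether RNA of adipocytes moved its position was not tested.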

How the results depend on the processing

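DESeq2, limma on all 12 libraries, the thinning of reads, the removal of GC and length trends, the replicate block and the interaction term were tests chosen after the result was seen. The direction of each named gene was kept in every alternative where it passed the threshold in the main or the alternative setting. In 29 values the direction turned with the threshold passed in neither setting. Over 7075 values of named genes, called or not, 6423 stayed on the same side of the threshold, 430 lost the call and 222 gained one. Of 1086 values for gene lists, 998 stayed on the same side, 52 lost the call, 35 gained one and 1 turned direction: secreted Wnt inhibitors at P28 without genes in more than 1 list (camera adjusted p = 0.0490). The largest shift of the median of all genes under another scaling was 0.0245 on the log2 scale (quantile normalization at P28). The groups share no number in the labels. Smo* and WT libraries with the nearest title numbers had deviations from their group means that correlated across genes at 0.128 to 0.289 at P20 (other pairs -0.234 to 0.0134) and at -0.0612 to 0.178 at P28 (-0.147 to 0.194), a hint of pairing at P20 from the data and not from the labels. As a replicate block these pairs gave 239 genes at P20 (100 of the 102 among them) and 1003 at P28 (918 shared), 2467 for the difference between ages and 72 shared by both ages, and at P20 the endothelial (camera adjusted p = 0.0280) and adipocyte (0.00506) lists gained a call. Read depth (at least 36323058 reads) limits only genes with few reads, where log2(value + 1) understates changes. Except where fewer libraries or another threshold make the difference, the cause was not tested.

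At P20 (102 genes) the count was 9 without a variance trend, 342 in the authors' deposited table, 481 with DESeq2 on 6 libraries (261 higher, 220 lower) and 358 on 12, 224 at an adjusted p of 0.1 and 9 at 0.01, and 8 (without WT replicate 2) to 129 (without Smo* replicate 1) with a library left out. At P28 (1313) it was 638 without a variance trend, 2880 in the authors' deposited table, 2058 with limma on 12 libraries, 2222 with DESeq2 on 6 and 2900 on 12, 2177 at 0.1, 405 at 0.01, 786 with a log2 fold change of at least 1, and 461 (without WT replicate 3) to 1619 (without Smo* replicate 3). With an estimated correlation camera called 0 lists at either age, where 4 at P20 and 1 at P28 had an unadjusted p under 0.05, fry called 2 and 3, and with no filter camera called 11 at P28. The difference between ages (1987) gave 1152 at 0.01, 1151 with a log2 difference of at least 1, 698 by the interaction term and 1260 (without P28 WT replicate 3) to 2209. Calls shared by both ages (41) numbered 86 at 0.1, 5 at 0.01 and 5 (without P20 WT replicate 2) to 50. P28 against P20 gave 1940 at 0.01, 1532 with a log2 fold change of at least 1 and 2336 (without P28 WT replicate 3) to 3139 in WT (3761), and 1575 with DESeq2, 1361 at 0.1, 33 at 0.01, 260 with a log2 fold change of at least 1 and 49 (without P28 replicate 1) to 1049 (without P28 replicate 3) in Smo* (511).

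Smo at P20 passed the threshold in the authors' deposited table (log2 fold change 0.46) and with DESeq2 (0.47 on 6 and on 12 libraries), and at P28 with quantile normalization (0.49), a mean of at least 50 (0.46), a pseudocount of 5 (0.46), limma on 12 libraries (0.46) and DESeq2 (0.46 on either), in the authors' deposited table (0.45), and without Smo* replicate 3 (0.49; range 0.39 to 0.50). Gli1 at P20 missed it with a mean of at least 50, without a variance trend and with robust empirical Bayes (1.63 in each) and with edgeR (1.57), and without each library (1.39 to 1.76) except WT replicate 3, without which it passed (1.95).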

Other observations

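The comparison of P28 with P20 within a genotype, the positions of single P20 libraries and the overlaps and covariances with the WT stage change were tests chosen after the result was seen.

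Several genes changed in opposite directions in Smo* at the ages compared, and apart from Galnt3 and Spock1 they were singled out after their values were seen. Galnt3, Ajap1, Kcnd3, Alx4, Smoc1 and Fblim1 were higher in Smo* at P20 (from 1.44 for Fblim1 to 3.00 for Galnt3 on the log2 scale) and lower at P28 (from -2.49 for Galnt3 to -0.96 for Ajap1), where independent lists would share 3.32 genes. In WT all 6 were higher at P28 than at P20, from 1.89 for Smoc1 to 5.92 for Galnt3. Dusp2, Sema5a and Spock1 were lower in Smo* at P20 (-1.35, -1.57 and -1.96) and higher at P28 (1.60, 0.65 and 1.63), where independent lists would share 1.27 genes, and in WT these 3 were lower at P28 (-3.53, -2.10 and -2.07). These WT changes use the same WT libraries as the Smo* effects, so they are not independent of them. Galnt3 and Spock1 differed between ages by -5.49 and 3.59 (interaction adjusted p = 7.96e-05 and 0.000685 by limma).

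Of 708 genes lower in Smo* at P28, 579 (81.8%) were called higher at P28 than at P20 in WT, where independent lists would share 97.1. Both comparisons use the P28 WT libraries, and lists of the same sizes from 50 simulations with no effects and those libraries shared had a mean of 357.5 genes in common (338 to 384). Of 596 genes higher in Smo* at P28, 329 (55.2%) were called lower at P28 in WT, against 71.0 for independent lists and 271.5 (250 to 293) in the simulations. In these simulations noise alone ranks the genes, so the shared libraries weigh more than in lists with real effects. The simulated counts therefore do not give the part of the real overlap that comes from shared libraries. Across 14102 genes the Smo* effect at P28 had a covariance of -0.523 with the WT change from P20 to P28, against -0.0792 in simulated data with no effects and the same shared WT libraries, and -0.519 to -0.428 with the P28 WT libraries split between the comparisons. The correlation across genes, which are not independent replicates, was -0.654, against -0.498 simulated and -0.607 to -0.463 with those libraries split. The P20 effect had a covariance of 0.133 (0.0799 simulated) and a correlation of 0.291 (0.501 simulated). The simulated correlations likewise come from noise alone, so they are no baseline for data with effects. On 3 axes from P20 WT (0) to P28 WT (1), each built without 1 P20 WT library, the P20 Smo* libraries lay at 0.145 to 0.198 and the left-out P20 WT libraries at 0.0535 to 0.0790, so on each axis the 3 Smo* libraries lay further toward P28 WT.

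Adipocyte markers did not pass the test at P28 (camera adjusted p = 0.0869) but did without P28 Smo* replicate 2 (0.000909) and with no filter (0.0276). At P20 (0.217) they passed without Smo* replicate 2 (1.50e-05). Adipoq, the adiponectin gene, lay at 25.3, 1.90 and 1018 normalized counts in P28 Smo* replicates 1, 2 and 3 and at 0 to 3.68 in P28 WT. Cfd, the adipsin gene, lay at 100.3, 0 and 8165 in these Smo* libraries and at 0 in P28 WT.

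The 6 libraries of each comparison of 3 with 3 can be split in 10 ways, which cannot give a share under 0.05. At P20, 1 split, the real one, called 102 genes (highest other 2) and 13 lists (highest other 11). At an unadjusted limma p under 0.05 the real split had 1669 genes and the others 230 to 1182. At P28, 1 split called 1313 genes by limma, and the highest other called 0 (the others had 68 to 520 genes at an unadjusted p under 0.05). For lists at P28, 8 of the 10 splits called at least the 6 of the real split (highest other 13), so camera with the preset correlation also called lists in splits that mix the genotypes. For P28 against P20 in WT, 1 split called 3761 genes by limma and the highest other 0. The others had 171 to 875 genes at an unadjusted limma p under 0.05. In Smo*, 1 split called 511 genes, with a highest other of 2. At an unadjusted limma p under 0.05 that split had 3368 genes and the others 277 to 1855.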
